A study of Mus musculus with 6 samples.

How the data were processed

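Total RNA from immortalized mouse embryonic fibroblasts (MEFs, connective tissue cells taken from embryos and grown in culture) was measured on 6 Affymetrix expression arrays, on which each probe set is a group of short probes for 1 transcript. All cells lacked PCAF (gene Kat2b). Per the labels, 3 arrays were from GCN5+/- and 3 from GCN5-/- cells. The design describes infection with a vector retrovirus or with one carrying Cre recombinase, an enzyme that removes the conditional part of GCN5 (gene Kat2a). No array label names the virus, and the design text writes GCN5+/- for both infections. The groups therefore follow the sample labels, and GCN5+/- was read as vector and GCN5-/- as Cre. In each group, replicates A1 and A2 were duplicate RNAs of line A and replicate B was from line B, a separately immortalized line. The p-values therefore rest partly on the spread between duplicate RNAs of 1 line, and only 2 independent lines stand behind them.

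The values analysed were log2 signals per probe set as deposited by the authors, between 3.13 and 15.2 over all arrays. The log2 scale was read from the values, since the sources used here do not state it. Per the submitters' processing notes, MAS5 was named for 6 samples and Partek for 1, with no role or order. The normalization method, background correction and any filter are not given in the sources used here. Array medians lay between 7.41 and 7.46 and the quartiles nearly coincided, so the values had been scaled between arrays before deposit. Normalization that equalizes arrays removes any change shared by most genes, and a log2 signal close to the floor compresses fold changes of weakly expressed genes. The values were not centred per gene, and no detection calls or scan dates were used here. Depth does not apply to arrays; the number of arrays limits the precision.

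The table held 45101 probe sets. Of these, 64 control probe sets were left out of the tests, which left 45037. The annotation table gave 34945 of them 1 gene symbol and 932 several, and 9160 are unnamed here. Symbols were checked through the Entrez identifier against the RefSeq gene table of GRCm38.p6, which was used for names only; 34754 identifiers matched. No gene was named from a probe set with several symbols. No coordinates are given, because the probe table names no genome build.

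Tests were run in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a trend of the variance on the mean). The genotype effect, GCN5-/- minus GCN5+/-, was fitted over all 6 arrays with cell line as a covariate. Probe sets entered the test where their mean log2 signal over the arrays was at or above the 40th percentile (6.80), which kept 27022 probe sets and 12626 named genes. Benjamini-Hochberg adjustment was used, and an adjusted p under 0.05 was called. The line effect came from the same fit, and the genotype by line interaction and the effect within line A from a fit with the product term, which has 2 residual degrees of freedom, all from the line A duplicates. Errors of log2 changes are standard errors (SE) of the fit. The Kat2a and Kat2b probe sets were read from a fit over all 45037 probe sets. RNA quality was followed as the ratio of 3 prime to 5 prime signal of the beta-actin and Gapdh control probe sets, with an exact two-sided permutation test whose smallest possible p is 0.1.

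The replicate names pair the arrays by cell line, since A and B name the same line in both groups; whether A1 of one group belongs with A1 of the other is not stated. Deviations from the group means correlated at 0.714 for the A1 arrays, 0.727 for the A2 arrays and 0.846 for the B arrays, and at 0.509 and 0.443 for A1 crossed with A2, so much of this is the shared line. Residuals of the fit with line correlated at 0.202 for A1 with A1 and 0.169 for A2 with A2, against -0.465 and -0.557 for the crossed pairs. Files of no 2 arrays were copies of each other: identical values were found for 38 to 62 probe sets per pair.

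Gene lists were written before the data were examined. Each of the 35 lists was tested, where at least 8 members passed the level filter, with camera at a preset correlation of 0.01 on 1 probe set per gene (the one with the highest mean signal); 32 lists were tested. As an alternative, the correlation was estimated for each list. Camera then uses only the residual degrees of freedom of the fit, 3 for the genotype effect and 2 for the interaction. It therefore has little power whatever the correlation. Members were matched by symbol, and 10 older symbols were renamed by hand. Named genes followed a rule also fixed before the data were examined: every Kat2a and Kat2b probe set; among called probe sets with 1 symbol and the same sign in the 3 matched pairs, the 12 genes with the largest rise and the 12 with the largest fall (1 probe set per gene, smallest p); up to 4 called members of each list, by smallest p; the 8 genes per direction with the largest line difference; and up to 5 genes per direction for the interaction. Genes named outside this rule are said to be so. Other than Kat2a, Kat2b and Xaf1, each named gene is given at 1 probe set. Some had other tested probe sets that were not called. Chek1 was called at 1 of 3, Vldlr at 2 of 5 and Rps18 at 2 of 4. Dlk1, Dgat2, Ncoa3, Slbp, Btg2, Bop1, Hsp90b1, Mt1 and Hoxa9 were each called at 1 of 2. Rian, Mcm3, Mcm5, Tigar, Polr1a, Xbp1, Hsp90aa1, Srxn1, Pmepa1 and Ltbp1 were called at most of theirs but not all.

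The procedure was tested on simulated data. For the genotype effect over 27022 probe sets, 76% of 50 simulated changes of 0.5 log2, 100% of 100 changes of 1 and 100% of 50 changes of 2 were recovered, with 19 false among 207 calls. For the interaction, 12%, 54% and 100% were recovered, with 12 false among 122 calls. A simulated shifted list was called and 0 of the other lists were. The simulated noise was independent between genes and between arrays. It therefore does not show how often lists of correlated genes are called without a change, nor what duplicates of 1 line do. Alternatives covered quantile normalization, centring on array medians, no level filter or the 60th percentile, no line term, a replicate block, line as a random block, averaged line A duplicates, eBayes without trend, a 2-fold threshold, probe sets with shared probes left out, each array left out in turn, and for lists an estimated correlation, fry and all probe sets.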

Results

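The study asked which genes depend on PCAF and GCN5, a pair of related histone acetyltransferases that can partly replace each other. All cells lacked PCAF, and the comparison is between cells with and without GCN5. Read from the study design, the GCN5-/- arrays are of cells given the Cre virus and the GCN5+/- arrays of cells given the vector, so the virus and the genotype changed together. Expression was measured in 3 GCN5+/- and 3 GCN5-/- arrays from 2 immortalized fibroblast lines, with 2 duplicate RNAs per group from line A and 1 RNA per group from line B. Median log2 signals were 7.46, 7.41 and 7.44 in the GCN5+/- arrays A1, A2 and B, and 7.44, 7.41 and 7.44 in the GCN5-/- arrays. The standard deviation (SD) of the log2 difference between duplicate arrays was 0.223 in the GCN5+/- group and 0.214 in the GCN5-/- group, against 0.547 between GCN5+/- A1 and GCN5+/- B. RNA quality ratios did not separate the groups. The beta-actin ratio was 1.06 ± 0.0229 (SD, n = 3) in GCN5+/- and 1.07 ± 0.00883 in GCN5-/- arrays (exact permutation p = 0.6). The Gapdh ratio was 0.935 ± 0.0155 (SD, n = 3) and 0.961 ± 0.0210 (exact permutation p = 0.2, adjusted p = 0.8 over the 4 ratios computed).

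The targeted gene was read first. Kat2a, which encodes GCN5, fell at 2 of its 3 probe sets. Probe set 1422972_s_at had a log2 signal of 10.30 ± 1.12 (SD, n = 3) in GCN5+/- arrays and 7.86 ± 0.11 in GCN5-/- arrays, a log2 change of -2.44 ± 0.36 (SE; limma adjusted p = 0.00823). Its signal was 9.31, 10.07 and 11.51 in GCN5+/- A1, A2 and B and 7.97, 7.85 and 7.75 in the matching GCN5-/- arrays. Probe set 1422971_at changed by -0.75 ± 0.13 (limma adjusted p = 0.0190). The third, 1426783_at, had a log2 change of 0.18 ± 0.16 and was not called (limma adjusted p = 0.670); it differed by 0.56 in pair A1, 0.38 in pair A2 and -0.41 in pair B. Where each probe set lies relative to the deleted part of the gene was not analysed here, so a probe set outside it checks nothing. The call of 1422972_s_at was lost without a line term (adjusted p = 0.214) and with averaged line A duplicates (adjusted p = 0.0519). Kat2b, knocked out in all samples, had 3 probe sets with mean signals between 4.92 and 6.78, below the level filter, and log2 changes of 0.19, -0.00 and 0.09 that were not called (limma adjusted p = 0.576, 0.999 and 0.762).

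**Figure D1:**
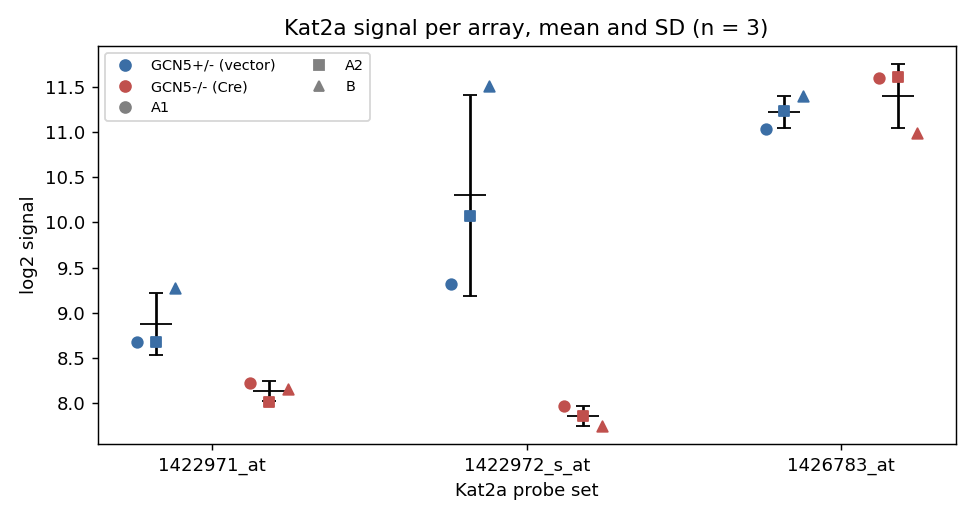
Log2 signal of the 3 Kat2a probe sets (horizontal axis) on each array, with the group mean and SD (n = 3); blue points are GCN5+/- and red points GCN5-/- arrays, and marker shapes give the replicate. At 1422972_s_at the GCN5-/- arrays lie between 7.75 and 7.97 and the GCN5+/- arrays between 9.31 and 11.51, while the groups overlap at 1426783_at.

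In GCN5-/- arrays, interferon-stimulated genes, the antiviral genes that interferon switches on, were higher (36 of 37 tested), while 17 of 26 cholesterol synthesis and SREBP target genes and 13 of 41 extracellular matrix genes were lower. In all, 2299 of 27022 probe sets were called, 1135 higher and 1164 lower in GCN5-/- arrays, for 751 and 720 named genes. Every one of the 2299 had the same sign in the 3 matched pairs. The calls come from these same differences, so this is no separate evidence that the pairs agree. At least 2-fold changes were seen at 204 higher and 97 lower probe sets. The median log2 change over tested probe sets was -0.01. Counts depended on how the line was treated: 69 probe sets were called without a line term (50 higher, 19 lower), 532 with line as a random block and 706 with averaged line A duplicates. Leaving out GCN5+/- A1 gave 725 calls, GCN5+/- A2 1115, GCN5-/- A1 1156 and GCN5-/- A2 636.

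Of the 12 genes with the largest rise, 7 were on the interferon-stimulated list. Oasl2, of the oligoadenylate synthetase family, rose by 4.59 ± 0.28 (log2, SE; limma adjusted p = 0.000144), from 7.09 ± 0.52 (SD, n = 3) to 11.68 ± 1.18. Usp18, a protease that removes the ubiquitin-like protein Isg15 and restrains interferon signalling, rose by 4.55 ± 0.09 (limma adjusted p = 8.05e-07), by 4.57, 4.53 and 4.55 in pairs A1, A2 and B. Iigp1, an interferon-inducible GTPase, rose by 3.79 ± 0.52, Ifit3 by 3.66 ± 0.23, Rtp4 by 3.41 ± 0.16, Gbp3, a guanylate-binding protein, by 3.40 ± 0.24, Trim30a by 3.33 ± 0.20 and Oas1a by 3.21 ± 0.45. The others were Ifi204 (3.09 ± 0.13), Ifit1 (3.05 ± 0.31), Zbp1, a sensor of nucleic acids (2.98 ± 0.47), and Lgals3bp (2.92 ± 0.11). Their adjusted p-values ran up to 0.00963 for Zbp1.

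Of the 37 interferon-stimulated genes tested, 36 rose and 0 fell, and 36 rose when adjusted over the list alone. The median log2 change was 2.14, with 2.24 in line A and 1.56 in line B. Usp18, Rtp4, Parp14 (2.69 ± 0.11, SE) and Igtp (2.61 ± 0.10) had the smallest p-values. The list was past the threshold by camera (adjusted p = 1.39e-40) but not with an estimated correlation (adjusted p = 0.203). Without a line term, 11 of the 37 were called. The single member not called was Irf1, named here after its values were seen, with a log2 change of 0.10 ± 0.09 (limma adjusted p = 0.565).

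**Figure D2:**
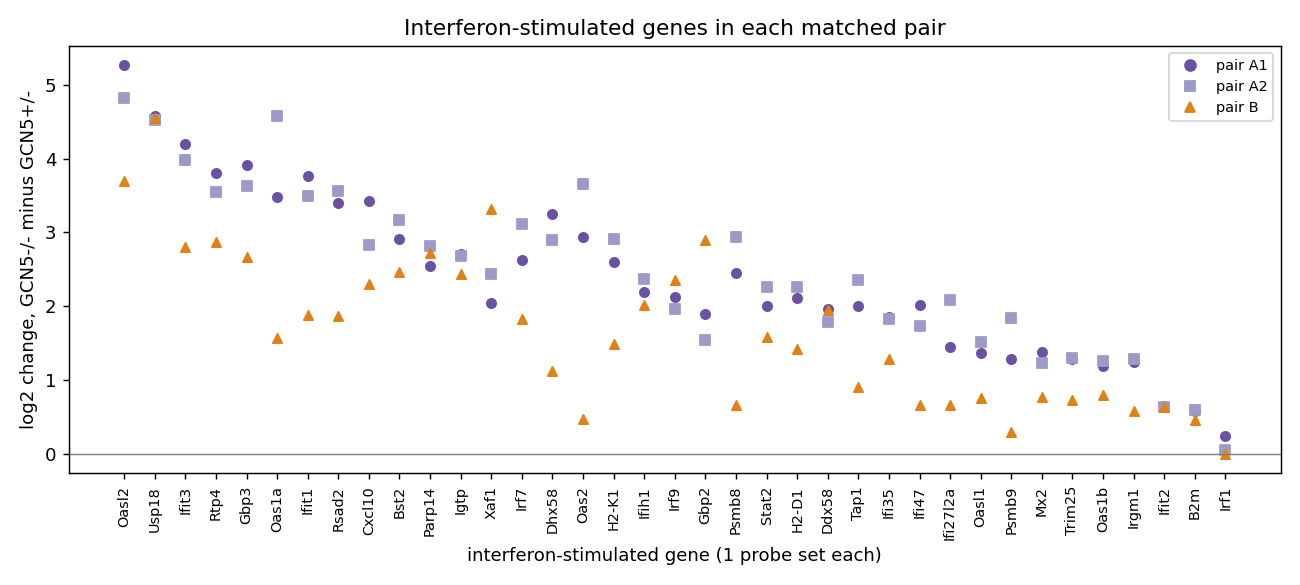
Log2 change (vertical axis, GCN5-/- minus GCN5+/-) of the 37 interferon-stimulated genes (horizontal axis, 1 probe set each) in the 3 matched pairs, 1 marker per pair. Usp18 lies near 4.55 in each pair, and 36 of the 37 genes were also higher in pair B.

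NF-kB and inflammatory genes rose as well: 13 of 22 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.52. The chemokines Cxcl1 (1.76 ± 0.09, SE), Ccl7 (1.43 ± 0.09), Ccl5 (1.44 ± 0.12) and Cxcl5 (1.86 ± 0.16) led it, with limma adjusted p-values up to 0.000626. Camera gave an adjusted p of 7.82e-11, and the adjusted p was 0.192 with an estimated correlation. Macrophage and leukocyte markers, which would follow other cells in the culture, had 1 member higher of 9 tested (2 adjusted over the list alone), Cd53 (0.85 ± 0.09), and were not past the threshold (camera adjusted p = 0.0715). Of markers of further cell types, neural markers had 0 of 9 called (2 lower adjusted over the list alone), with a median of 0.01 although the test pointed down (camera adjusted p = 0.479). Of skeletal muscle genes 0 of 5, of endothelial genes 0 of 7 and of epithelial genes 0 of 7 were called, too few to test as lists. Adjusted over the list alone, 2 endothelial genes were lower, Flt1 (-0.51 ± 0.16) and Egfl7 (-0.42 ± 0.13), both named outside the rule.

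Fmod (fibromodulin, a collagen-binding proteoglycan) fell by 2.62 ± 0.50 (log2, SE; limma adjusted p = 0.0198), and Fbn2 (fibrillin) by 2.24 ± 0.13 (limma adjusted p = 0.000115). Col14a1 fell by 1.68 ± 0.18, Aspn by 1.64 ± 0.18 and Lum by 1.56 ± 0.40. The adjusted p of Lum lay just under the threshold, and was 0.0567 with quantile normalization and 0.0693 with the replicate block. Of the 12 genes with the largest fall, 1 was on the extracellular matrix list, and Kat2a was also among them. The others were Cxcl15 (-1.89 ± 0.39), the receptor gene Epha3 (-1.72 ± 0.26), Islr (-1.68 ± 0.14), the maternally expressed RNA Rian (-1.52 ± 0.13), Mc2r (-1.50 ± 0.31) and Ndnf (-1.47 ± 0.22). Differences at Fmod were -3.53 and -3.71 in pairs A1 and A2 and -0.63 in pair B.

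Among 41 fibroblast extracellular matrix genes, 13 fell and 1 rose (18 and 2 adjusted over the list alone), with a median of -0.16. Col1a1 fell by 0.35 ± 0.03 (SE), Postn (periostin) by 0.93 ± 0.14 and Col11a1 by 1.37 ± 0.21, while Timp1, an inhibitor of matrix proteases, rose by 0.31 ± 0.04. Camera gave an adjusted p of 8.38e-07, and 0.203 was the adjusted p with an estimated correlation. Smooth muscle and myofibroblast markers had 4 lower and 1 higher of 14 (7 and 1 adjusted over the list alone; median -0.16, adjusted p = 0.0105, and adjusted p = 0.287 with an estimated correlation). Myl9 fell by 0.69 ± 0.10, Actg2 by 0.52 ± 0.10 and Tpm1 by 0.21 ± 0.04, and Cnn1 rose by 0.46 ± 0.09. Matrix proteases had 1 higher (Plaur, 0.51 ± 0.11) and 1 lower (Mmp14, -0.89 ± 0.14) of 19 (4 and 4 adjusted over the list alone), and the list was not past the threshold (adjusted p = 0.900), its median of 0.03 lying opposite to the direction of the test. Chondrocyte and osteoblast markers had 2 lower of 10 (2 adjusted over the list alone), Mgp (-0.60 ± 0.08) and Omd (-0.69 ± 0.13), at an adjusted p of 0.136.

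Most cholesterol biosynthesis and SREBP target genes were lower, and 9 were not called. Of 26 tested, 17 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of -0.54, -0.55 in line A and -0.39 in line B. Cyp51 fell by 0.93 ± 0.09 (SE), Hmgcs1 by 0.87 ± 0.09, Mvk (mevalonate kinase) by 0.83 ± 0.10 and Sqle (squalene epoxidase) by 0.67 ± 0.05. Camera gave an adjusted p of 2.96e-14, and the adjusted p was 0.398 with an estimated correlation. PPAR and fatty acid oxidation genes went both ways, with 3 higher and 2 lower of 19 (3 and 4 adjusted over the list alone; adjusted p = 0.727): Angptl4 rose by 1.49 ± 0.13, Plin2 by 0.53 ± 0.06 and Acadvl by 0.45 ± 0.07, and Acot1 fell by 0.67 ± 0.12. Adipogenic genes had 1 higher and 2 lower of 13 (1 and 4 adjusted over the list alone; adjusted p = 0.120), with Dlk1 at -1.21 ± 0.17, Fabp4 at -0.54 ± 0.13 and Dgat2 at 0.66 ± 0.15.

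Growth and metabolism lists had larger medians in line A than in line B. Myc target and ribosome biogenesis genes had 7 higher and 0 lower of 30 (17 and 1 adjusted over the list alone), with medians of 0.31 in line A and 0.05 in line B; Bop1 rose by 0.67 ± 0.09 (SE), Myc by 0.54 ± 0.09, Polr1a by 0.52 ± 0.12 and Nop56 by 0.34 ± 0.07. DNA replication and S phase genes had 8 higher and 0 lower of 37 (13 and 0 adjusted over the list alone), with medians of 0.23 and 0.05; Mcm5 rose by 0.40 ± 0.07, Mcm6 by 0.36 ± 0.05, Mcm3 by 0.35 ± 0.06 and Slbp by 0.33 ± 0.06. Hypoxia and glycolysis genes had 10 higher and 1 lower of 25 (13 and 2 adjusted over the list alone), with medians of 0.28 and 0.10; Pdk1 rose by 0.63 ± 0.10, Bnip3 by 0.57 ± 0.09 and Pgk1 by 0.25 ± 0.04, and Adm fell by 0.89 ± 0.14. Camera adjusted p-values were 2.03e-07, 0.000199 and 8.50e-05 for the 3 lists, and with an estimated correlation the adjusted p-values were 0.557, 0.557 and 0.398. For the difference between the lines, camera on the interaction gave adjusted p-values of 8.02e-11, 4.60e-07 and 0.00111, and with an estimated correlation the adjusted p-values were 0.572, 0.721 and 0.572. Oxidative phosphorylation had 2 higher of 34 (0 adjusted over the list alone), Ndufs3 (0.23 ± 0.06) and Atp5b (0.13 ± 0.03), and DNA damage repair 2 higher of 23 (3 adjusted over the list alone), Xrcc6 (0.35 ± 0.09) and Chek1 (0.37 ± 0.09); their adjusted p-values were 0.00380 and 0.00344, and the adjusted p was 0.557 for both with an estimated correlation. With the replicate block Ndufs3, Atp5b and Xrcc6 were not called (adjusted p = 0.0619, 0.0653 and 0.0528).

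Cytosolic ribosomal protein genes had 8 lower and 0 higher of 22 (13 and 0 adjusted over the list alone), by small amounts with a median of -0.11: Rpl38 fell by 0.31 ± 0.03 (SE), Rps15 by 0.23 ± 0.03, Rps18 by 0.16 ± 0.03 and Rpl8 by 0.14 ± 0.03. The list was past the threshold (adjusted p = 5.53e-06; adjusted p = 0.192 with an estimated correlation). Wnt pathway genes had 6 lower of 21 (9 adjusted over the list alone; median -0.28), with Fzd1 at -1.15 ± 0.18, Rspo3 at -1.14 ± 0.25, Sfrp2 at -1.09 ± 0.19 and Fzd2 at -0.57 ± 0.10 (adjusted p = 7.61e-05, and adjusted p = 0.192 with an estimated correlation). Hox genes had 3 lower of 18 (6 adjusted over the list alone; median -0.20), Hoxb9 (-0.59 ± 0.14), Hoxa7 (-0.46 ± 0.09) and Hoxa9 (-0.38 ± 0.10), at an adjusted p of 0.000984, and an adjusted p of 0.287 with an estimated correlation. Senescence and INK4 locus genes had 6 lower and 1 higher of 11 (7 and 1 adjusted over the list alone; median -0.47): the cell cycle inhibitors Cdkn1c (-1.42 ± 0.11), Cdkn2b (-0.49 ± 0.07) and Cdkn2c (-0.47 ± 0.07) fell, and Il6, an inflammatory cytokine, rose by 1.62 ± 0.21 (adjusted p = 0.000690, and adjusted p = 0.410 with an estimated correlation).

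The remaining lists were not past the threshold. SAGA and ATAC complex subunits, the partners of GCN5, had 1 higher of 25 (0 adjusted over the list alone), Taf5l (0.39 ± 0.09, SE), at an adjusted p of 0.668; Kat2a entered that list through 1426783_at, its brightest probe set. Other histone acetyltransferases and bromodomain readers had 1 lower of 15 (1 adjusted over the list alone), Ncoa3 (-0.41 ± 0.10; adjusted p = 0.119), and histone deacetylases and sirtuins 0 of 17 (adjusted p = 0.592). G2 and mitosis genes had 0 of 35 called (adjusted p = 0.900). The p53 target genes went both ways, with 2 higher and 2 lower of 29 (5 and 5 adjusted over the list alone; adjusted p = 0.930): Tigar (0.51 ± 0.11) and Rrm2b (0.44 ± 0.09) rose, and Btg2 (-0.58 ± 0.12) and Phlda3 (-0.41 ± 0.09) fell. TGF-beta and BMP response genes had 2 higher and 4 lower of 24 (2 and 6 adjusted over the list alone; adjusted p = 0.0752), with Bmp4 at -0.89 ± 0.08, Tgfb3 at -0.79 ± 0.12, Pmepa1 at -0.58 ± 0.08 and Ltbp1 at 0.32 ± 0.06. Immediate early and serum response genes had 6 higher and 2 lower of 31 (7 and 2 adjusted over the list alone; adjusted p = 0.467, median -0.00 with an upward test), including Fosl1 (1.02 ± 0.14), Dusp5 (0.80 ± 0.11), Ier3 (0.51 ± 0.06) and Spry1 (-0.67 ± 0.10).

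Stress and housekeeping lists were not past the threshold either. For scale, 8.51% of all tested probe sets were called. The integrated stress response and unfolded protein response had 3 lower of 29 (3 adjusted over the list alone; adjusted p = 0.0579), Xbp1 (-0.59 ± 0.08, SE), Vldlr (-0.46 ± 0.10) and Hsp90b1 (-0.26 ± 0.06). Heat shock genes had 2 higher of 12 (2 adjusted over the list alone; adjusted p = 0.355), Hspa1b (0.38 ± 0.08) and Hsp90aa1 (0.23 ± 0.03). NRF2 oxidative stress genes had 1 higher and 1 lower of 20 (1 and 1 adjusted over the list alone; adjusted p = 0.228), Srxn1 (0.45 ± 0.09) and Mt1 (-0.39 ± 0.07). Autophagy and lysosome genes had 2 higher of 25 (2 and 2 adjusted over the list alone; adjusted p = 0.901), Ctsz (0.41 ± 0.06) and Gabarapl2 (0.28 ± 0.06). Circadian clock genes had 1 lower of 17 (1 higher and 3 lower adjusted over the list alone; adjusted p = 0.897, with a median of 0.04 opposite to the test), Dbp (-0.87 ± 0.14).

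Over the 32 lists tested, 14 were past the threshold by camera, 7 up and 7 down. None of the 14 held with an estimated correlation (0 lists, lowest adjusted p = 0.192), and 5 lists had an unadjusted p under 0.05. That test also rests on only 3 residual degrees of freedom, so lost calls are not by themselves evidence of correlated genes. Cytosolic ribosomal proteins (estimated correlation -0.018), Wnt pathway genes (-0.0209) and smooth muscle markers (-0.0391) lay below the preset 0.01 and still lost their call. Fry, which asks whether a list's own genes move one way, put 11 lists past the threshold. Other splits of the 6 arrays put up to 16 lists past it, so the list counts need caution. Each of those splits mixes the genotypes, so they do not rank the list counts against the calls of single genes.

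**Figure D3:**
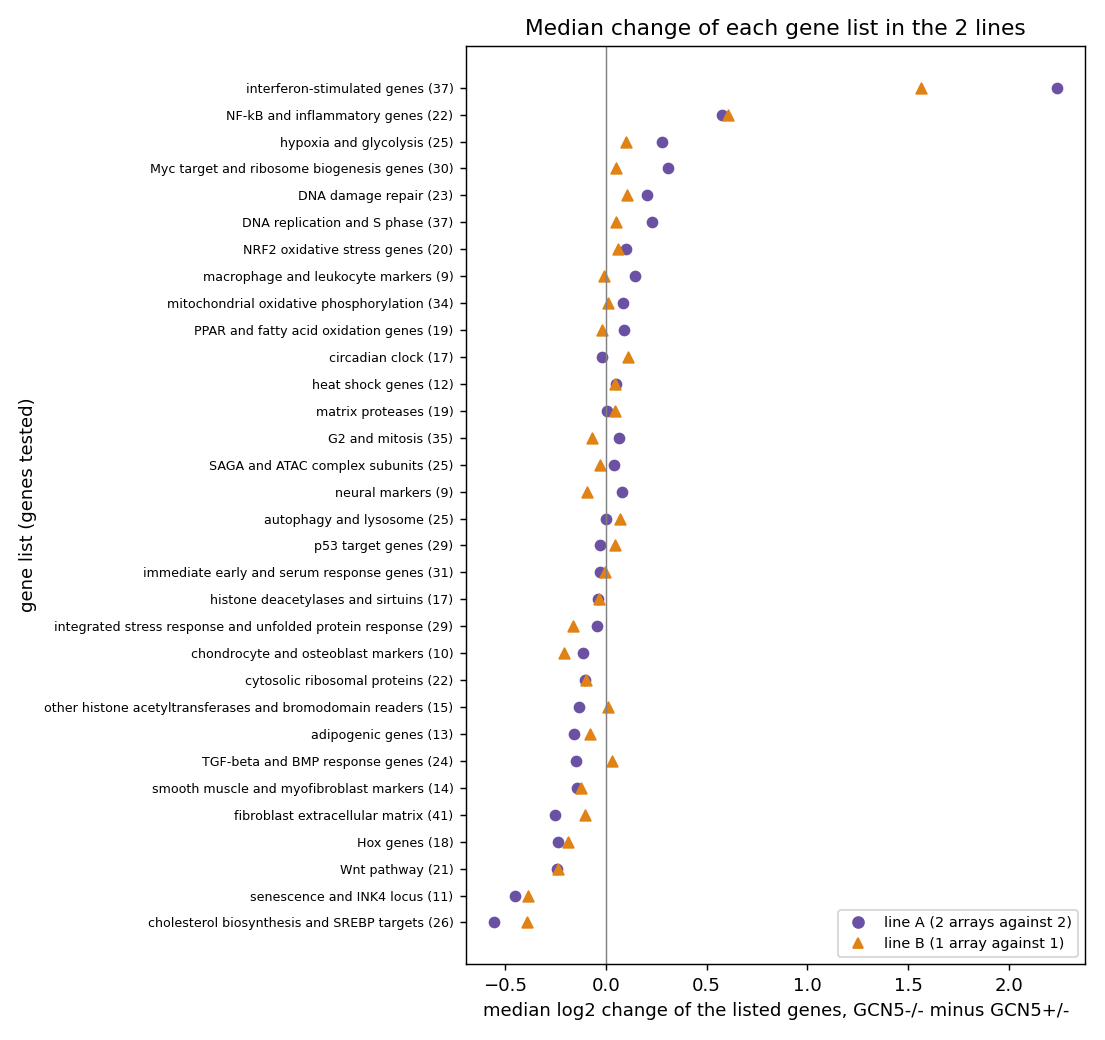
Median log2 change (horizontal axis, GCN5-/- minus GCN5+/-) of the 32 gene lists tested (vertical axis, number of genes tested in brackets), with circles for line A and triangles for line B. Interferon-stimulated genes lie at 2.24 and 1.56, cholesterol genes at -0.55 and -0.39.

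More probe sets differed between the 2 lines than between the genotypes. Between lines, 6246 probe sets were called, 3129 higher and 3117 lower in line B. Efemp1, a matrix glycoprotein gene, had a log2 signal of 5.85 ± 0.21 (SD, n = 4) in line A and 13.11 ± 0.02 (n = 2) in line B, a difference of 7.27 ± 0.14 (SE; limma adjusted p = 8.63e-08). Epb41l4a (4.71), Gatm (4.70), the mesothelial marker Msln (4.66), Sema5a (4.14), Evi2a (4.04), Crabp1 (3.93) and Capn6 (3.76) followed. The imprinted gene Grb10 was at 13.93 ± 0.16 in line A and 5.92 ± 0.05 in line B, a difference of -8.01 ± 0.08. Igfbp2 (-6.10), the germ cell gene Ddx4 (-5.60), Shox2 (-5.23), Cemip (-5.09), Rasl11a (-4.89), Mgst1 (-4.84) and Ebf3 (-4.66) followed. Each line is 1 immortalization, so this compares these lines only; without GCN5+/- B the count was 2994.

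Did the genotype effect differ between the lines? The interaction called 13 probe sets, 6 with a change more positive and 7 with a change more negative in line B, and 2071 had an unadjusted p under 0.05. Fmod (interaction 2.99 ± 0.22, SE; limma adjusted p = 0.0131) and Sorbs2 (2.23 ± 0.21, adjusted p = 0.0303), an actin-linked adaptor, had differences of -3.62 and -2.10 in line A and of -0.63 and 0.13 in line B. Xaf1 at 1443621_at rose by 3.76 in line A and differed by 0.23 in line B (interaction -3.53 ± 0.22, adjusted p = 0.00631), whereas another Xaf1 probe set, 1443698_at, differed by 2.04, 2.44 and 3.31 in pairs A1, A2 and B. Iigp1 rose by 4.81 in line A and differed by 1.75 in line B (-3.06 ± 0.27, adjusted p = 0.0262). Crabp1, Lum and Lrrc15 had line B differences of -2.58, -3.11 and -2.05 against -0.24, -0.79 and 0.16 in line A (limma adjusted p = 0.0303, 0.0437 and 0.0437). With quantile normalization Sorbs2, Iigp1, Crabp1, Lum and Lrrc15 were not called (limma adjusted p = 0.0721, 0.0628, 0.0628, 0.104 and 0.0628), nor was Crabp1 with the level filter at the 60th percentile (limma adjusted p = 0.0648). The count was 4 with quantile normalization, 47 with arrays centred on their medians and 53 to 103 without 1 of the line A arrays. With 1 array per genotype in line B, its spread was taken from the line A duplicate RNAs, so these calls do not show that independent samples of the lines would differ.

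Within line A alone, against the spread of its duplicate RNAs, 2322 probe sets were called, 1135 higher and 1187 lower. Of these, 2011 (86.6%) had the same sign in line B, and the share was 84.4% to 89.5% without 1 of the line A arrays. Across the 27022 probe sets, which are not independent replicates, the log2 differences of the lines correlated with Pearson r = 0.594 and Spearman rho = 0.458. The lines shared no control array.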

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

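The tests of leukocyte RNA, of line A alone, of the Cre virus, of the starting level and of the Kat2a signal, and the comparison of spike-in controls, were chosen after the results were seen. The interaction of genotype and line was called at 13 probe sets, measured against the spread of duplicate RNAs of line A alone, since line B has 1 array per genotype; whether independent samples of the lines would differ was not tested. The difference, line B minus line A, was 2.99 for Fmod, 2.23 for Sorbs2, -3.53 for Xaf1 at 1443621_at, -3.06 for Iigp1, -2.34 for Crabp1, -2.32 for Lum and -2.21 for Lrrc15.

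By camera on the same interaction, with the same limit, 14 lists were past the threshold at the preset correlation. With an estimated correlation 0 were, and 0 lists had an unadjusted p under 0.05. That test rests on 2 residual degrees of freedom, so it could hardly have called a list. No difference of whole lists between the lines is claimed, and none is excluded. Median interactions, line B minus line A, were -0.69 for interferon-stimulated genes (adjusted p = 0.572 with an estimated correlation), -0.32 for Myc target and ribosome biogenesis genes, -0.23 for DNA replication and S phase, -0.14 for hypoxia and glycolysis, -0.13 for the integrated stress response, -0.11 for G2 and mitosis and -0.10 for oxidative phosphorylation. They were 0.21 for TGF-beta and BMP response genes, 0.20 for cholesterol biosynthesis, 0.16 for matrix proteases, 0.11 for NF-kB genes, 0.11 for extracellular matrix, 0.0752 for the senescence list and 0.0422 for autophagy and lysosome.

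At Kat2a 1426783_at, pair B differed by -0.41 against 0.56 and 0.38 in the line A pairs; this difference between lines was not tested on its own. The control probe sets for a Cre spike-in, relative to the Bio spike-in controls, were 3.46 ± 0.05 (SD, n = 3) in GCN5+/- and 3.59 ± 0.06 in GCN5-/- arrays, a log2 difference of 0.14 with no overlap (exact permutation p = 0.1, the smallest possible). Whether these probe sets also read Cre RNA made by infected cells was not tested. The difference therefore does not settle which arrays received the Cre virus.

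Interferon-stimulated genes were higher in GCN5-/- arrays. Leukocyte RNA would bring leukocyte markers up with them, but the median change of the 18 markers measured was 0.0852, with a median absolute deviation of 0.168, against 2.14 and 1.05 for the interferon-stimulated genes. Cd53 was the only marker called higher (0.85 ± 0.09, SE), while Mpeg1, Cd68 and Csf1r had log2 changes of 0.76, 0.38 and 0.36 and were not called, so the tables argue against leukocytes as the source of the whole rise, not against a few in the culture. An event in line A alone is argued against by line B, where the median change was 1.56 and 36 of 37 genes were higher, while the GCN5+/- arrays of the 2 lines differed by a median of 0.375. Cre virus exposure and loss of GCN5 cannot be told apart, since virus and genotype changed together as the design is read here, so either may be the source. The labels could not test this, because no array label names the virus.

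In line B the median rise of the interferon-stimulated genes was smaller, 1.56 against 2.24, although the difference was not past the threshold with an estimated correlation (adjusted p = 0.572). A higher starting level in line B cannot be told apart with 1 GCN5+/- array there, which lay -0.20 relative to line A over these genes. Nor can less complete loss of Kat2a, where the GCN5-/- array of line B lay -0.16 relative to line A at the responding probe set, at a signal not shown to be above background. A smaller genotype effect over all genes also remains open: the median ratio of the line B to the line A change was 0.667 for 36 called interferon-stimulated genes and 0.812 for 1209 other called genes, and 95% of 10000 random sets of the latter gave 0.646 to 1.02. Genes called over both lines are picked partly for agreement, so both ratios may lie too near 1. Over probe sets called within line A, the slope of the line B on the line A change was 0.555. That choice of probe sets leans the other way. The random sets also ignore correlation between genes. A biological difference between the lines is untested.

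Splits of the 6 arrays into 3 against 3 number 10, too few for a share under 0.05. The real split called 2299 probe sets (1 of 10 splits reached that count) and the highest other 0. For interferon-stimulated genes called in one direction, the real split gave 36 (1 of 10 splits), and the highest other 0. For gene lists, 3 of 10 splits gave as many as the real 14, and the highest other gave 16. The 3 other splits that part all 3 pairs, as the real one does, gave 0 calls and 5 to 12 lists. Every other split mixes the genotypes, so the genotype effect enters its residual spread. Counts of 0 calls there were largely fixed beforehand, and list counts there can still carry part of that effect.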

How the results depend on the processing

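The counts of interferon-stimulated genes higher, and the fits without 1 line A array for the interaction, the effect within line A and the agreement of the lines, were added after the data were seen. Of the named genes, lists and counts that were followed under each alternative, none changed sign while called; the sign of the other called probe sets was not followed. The pseudocount alternatives were not run, because the deposited values are already log2. The replicate block (A1, A2 and B) gave 2627 calls, 36 interferon-stimulated genes higher and 14 lists, all within 1.5 times of those without it. Pairing ended the calls of 4 of 113 named probe sets (Lum, Ndufs3, Atp5b and Xrcc6) and changed no other call of a named probe set or list. Against 2299 calls for the genotype effect, 69 were found without a line term (72.5% higher, against 49.4%), 532 with line as a random block, 706 with averaged line A duplicates, 1456 without probe sets ending in _x_at, _s_at or _a_at (fewer probe sets tested) and 301 with a 2-fold threshold (67.8% higher). Without a line term the difference between lines enters the residual spread; there, 11 interferon-stimulated genes were higher and the Kat2a change of -2.44 was no longer called, nor was it (-2.77) with averaged duplicates. The interaction gave 4 calls with quantile normalization, 47 with arrays centred on their medians, 27 with no level filter and 4 at the 60th percentile; the cause was not tested. The correlation of the lines was 0.514 with no level filter and 0.634 at the 60th percentile. With an estimated correlation 0 lists were past the threshold, against 14. Leaving out 1 array at a time gave 636 to 2321 calls for the genotype effect, 32 to 37 interferon-stimulated genes higher, 2994 to 5395 for the line effect, 53 to 103 for the interaction, a correlation of 0.506 to 0.616 and 84.4% to 89.5% of line A calls with the same sign in line B. Without a B array the genotype effect rests on line A alone, and the interaction has no value; without a line A array, the lone array left in its group is assumed to vary like the duplicates. Of the named probe sets, 100 of 113 lost their call without a line term, 66 of 108 with line as a random block and 57 of 112 with averaged duplicates. The totals of 113 and 112 also count Kat2a and Kat2b probe sets, most of which were not called in the main fit. The genotype effect stayed within 1.5 times of its count with quantile normalization (2401), arrays centred on their medians (2565), no level filter (2012), the 60th percentile (2249) and no trend (1638). Signals close to the floor limit what can be measured of weakly expressed genes.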

Other observations

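The lists of imprinted genes and of interferon ligands, receptors and sensors were written, and the tests on them chosen, after the genotype effect was seen; Dlk1, Cdkn1c, Ifih1, Ddx58, Dhx58 and Zbp1 also belong to lists or a naming rule fixed before. Imprinted genes are expressed from only 1 parental copy in at least some tissues. Whether that held for each gene in these fibroblasts was not tested. Of 29 tested, 12 fell and 0 rose, but 10 of the 29 had prompted the list; of the other 19, 3 fell and 0 rose, with a median log2 change of -0.13. Igf2, a fetal growth factor, changed by -1.37 ± 0.08 (SE; limma adjusted p = 0.000101), Mest by -1.44 ± 0.24, Cdkn1c by -1.42 ± 0.11, Peg3 by -1.24 ± 0.29, Mirg by -1.24 ± 0.19, Dlk1 by -1.21 ± 0.17, Meg3 by -1.05 ± 0.16 and, not among those that prompted the list, Ndn by -0.63 ± 0.09. Both maternally expressed genes (Meg3, Cdkn1c) and paternally expressed ones (Igf2, Mest, Peg3) were among them. Gnas, Igf2r and Snrpn had log2 changes of -0.05, -0.17 and 0.02 and were not called.

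Among 11 tested interferon ligands, receptors and sensors, 2 rose and 0 fell (median log2 change 0.07). This list leaves out sensors already described or on the interferon-stimulated list, which rose: Ifih1 by 2.19 ± 0.15 (SE), Ddx58 by 1.90 ± 0.10, Dhx58 by 2.42 ± 0.34 and Zbp1 by 2.98 ± 0.47. Ifnb1 had a mean log2 signal of 6.23 in GCN5+/- and 6.34 in GCN5-/- arrays (log2 change 0.11 ± 0.10, limma adjusted p = 0.665 over all probe sets), and Ifng was at 4.69 and 4.81. Ifna1, Ifna2 and Ifna4 had log2 changes of -0.13, 0.00 and 0.11 and were not called. The double-stranded RNA sensor Tlr3 rose by 1.63 ± 0.16 (limma adjusted p = 0.00136) and the RNA-editing enzyme Adar by 0.99 ± 0.10 (limma adjusted p = 0.00173). The receptor genes Ifnar1 (-0.37 ± 0.13) and Ifnar2 (-0.19 ± 0.10) were not called. Interferon made at a level below detection by these probe sets is not excluded by such values.

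The fall of imprinted genes was tested on the 19 genes that had not prompted the list. A share of 0.00350 of 10000 random lists matched on level had a median as low, which argues against a chance draw of single genes. But camera with an estimated correlation between genes, which rests on 3 residual degrees of freedom, gave p = 0.0549. The genes that prompted the list include the neighbours Dlk1, Meg3, Rian and Mirg, and that p leaves open whether these and the other 6 carry the fall. An event in line A alone stays open too: in line B the median of the 19 genes was -0.12, with 12 lower, and a share of 0.0236 of random lists had a line B median as low, from 1 array per genotype. Loss of GCN5 and Cre virus exposure cannot be told apart here, and a wider fall of imprinted genes is no more than a hypothesis that these data leave open.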
